A study of Mus musculus with 2 samples.

How the data were processed

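The series compared the ventral prostate of mice that carry an ARR2PB-miR32 transgene with that of wild-type mice at 6 months of age. ARR2PB is a composite probasin promoter that drives expression in prostate epithelium under androgen control. Per the labels, the mice were of the FVB/N strain (the strain is also spelled FBV/N there), and total RNA was extracted with Trizol. RNA of 6 wild-type mice was pooled, and RNA of 6 transgenic mice was pooled. Per the labels, 100 ng of RNA was labelled with the Agilent Low Input Quick Amp kit, one pool in Cy3 and the other in Cy5, and both were hybridised together to a whole mouse genome array. The pair of pools was hybridised 2 times. On array 1 the transgenic pool was in Cy3, and on array 2 the dyes were swapped and it was in Cy5. The growth text of the labels speaks of ventral or dorsolateral prostates, while the tissue of both arrays is given as ventral prostate.

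Per the file headers, the spots were read with Agilent Feature Extraction 11.0.1.1, and the array's annotation build is mm9. The deposited scanner files give, for each dye, the intensity of each spot and of its local background as median pixel values with no normalization. They also hold processed intensities, which per the file headers were background-subtracted and dye-normalized, and a log10 ratio of red (Cy5) over green (Cy3) made from them. The deposited table of the whole series holds 15511 probes on a log2 scale. Its scale and direction were found by comparison with the scanner files. Each column correlated at r = 0.99994 and r = 0.99997 across probes with the log2 ratio of processed signals turned to transgenic over wild type, after a constant of -0.08 on array 1 and -0.05 on array 2. Each column's median was 0. All of its probes other than 37 control probes were well above background in both pools on both arrays. The filter that made this table is not given in the sources used here.

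Each array has 45018 spots, of which 1639 are controls. There were 41174 different probes, and 245 of them were printed as 10 spots. Feature Extraction marked 448 spots on array 1 and 299 on array 2 as outliers, and no spot was saturated (0 spots). Per the file headers, green signals of non-control spots were well above background for 29736 spots on array 1 and 30718 on array 2, and red signals for 18606 and 17185. The median coefficient of variation of replicate probes was 15.1% and 15.7% in green and 30.5% and 25.9% in red. The red values lay outside Feature Extraction's own range on both arrays. The mean local background was 26.2 and 26.4 in green and 114 and 117 in red.

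Background was corrected with normexp (offset 50) and ratios were normalized by loess within each array, with limma 3.58.1 in R 4.3.3. Control spots and outlier spots had weight 0 in the loess. The design named mean foreground signals, and the deposited files carry median signals, so medians were used. Spots of a probe were averaged without outlier spots. Each array's log2 ratio was turned to transgenic over wild type by the dyes in the labels, and the 2 arrays were averaged, so that a dye effect cancels. A probe counted as detected where it was well above background on both arrays in the channel of at least 1 of the pools. This left 18113 probes, of which 15486 were well above background in both pools. Each gene was represented by its detected probe of highest mean intensity, which gave 13903 genes.

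The files carry accessions and no gene symbols. Symbols came from a RefSeq gene table of the assembly GRCm38.p6, matched on accession without version, and 27816 probes matched while 13358 did not. That assembly differs from the build of the files, so it served for names alone and no coordinates are given. Of the detected genes, 10967 carried a symbol.

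The arrays measure the same 2 RNA pools, so they are technical replicates and each genotype has 1 replicate. No significance test was run and no p-value is given. A gene was called higher or lower where its mean log2 ratio was at least 1 in size and its ratio was at least 1.5-fold in the same direction on each array alone. As a description of technical error, the rule was applied again after the sign of 1 array was turned. Where a gene was well above background in the transgenic pool on neither array by any of its probes, the difference is a bound, written as at least N-fold. Where 1 of the 2 arrays measured it there, the ratio is given as it is. The bound sets the wild-type mean against the higher of the transgenic signal and the lowest signal among probes well above background, per channel after loess and Aquantile normalization. Where the transgenic signal is the higher, the bound equals the measured mean ratio and carries its technical error.

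There were 34 gene lists, for prostate functions, cell types and pathways. For each list of at least 5 detected members, the median log2 ratio was placed as a percentile among 10000 random gene lists of the same size matched on mean intensity in 20 bins. A list was said to stand apart outside the central 95% of the random medians. The genes named are the 12 highest and 12 lowest called genes with a usual symbol, up to 4 called members per list with the largest ratio, and a panel of 12 genes given whatever their values. Some genes that this rule takes are not reported here. Rac2, Casp1, Sbpl, Ifit1, Irf1, Fabp3, Cox7a1, Ear1, Scgb1b27, Wfdc18, Igtp and Tgtp1 were named after their values were seen. So were list members described as not called and the medians of 4 gene families. A brown fat list was added after the data were examined, but before the values of its own genes were looked at. The rule, the 34 lists, the panel and the alternatives were fixed before the data were examined.

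The alternatives were no background subtraction, an offset of 16, the log10 ratios of Feature Extraction, median centring in place of loess, the values of the series table, no filter on dim probes, detection in both pools, the mean of a gene's detected probes, each array alone, other fold rules, and random lists not matched on intensity. A planned comparison of genes with and without miR-32 seed matches needs 3' UTR sequences, which were not used here. MicroRNA levels were not measured on these arrays.

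The procedure was tested on simulated data made for the comparison of transgenic with wild type over 12576 bright probes, each treated as a gene. Of 50 probes changed at each size, it called 1 at 1.5-fold, 11 at 2-fold, 50 at 4-fold and 50 at 8-fold. It called 0 of 12376 unchanged probes, and a shifted list stood apart while an unchanged list did not. The simulation holds technical noise alone, without outlier spots. Dim probes were not scored, so it does not show how often signals near background give a false call. The number of arrays limits the precision of each value, and differences among mice within a pool cannot be seen.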

Results

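Gene expression in the ventral prostate was measured on 2 two-colour Agilent whole mouse genome arrays. Each array carried a pool of RNA from 6 wild-type mice and a pool from 6 mice with an ARR2PB-miR32 transgene, all at 6 months of age, and the dyes were swapped between the arrays. miR-32 is a microRNA of the miR-25/92 seed family, and the comparison asks what its expression in prostate epithelium does to the messenger RNAs of the gland. Both arrays measured the same pair of RNA pools, so each genotype had 1 replicate and no difference below has a replicate check. Values are mean log2 ratios of transgenic over wild type, with the SD of the 2 technical arrays (n = 2), which leaves out the spread between mice.

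More genes were lower than higher in the transgenic pool. Of 13903 detected genes, 151 were higher and 491 were lower in the transgenic pool by the rule of a mean log2 ratio of at least 1 in size with at least 1.5-fold in the same direction on each array. Of these, 128 higher and 314 lower genes carried a usual symbol. The other 23 higher and 177 lower ones had other names, and an accession without a symbol was counted as 1 gene. For 24 of the lower genes the transgenic pool was well above background on neither array, so their differences are bounds. By the probe used, the transgenic pool was well above background on 1 of the 2 arrays for 200 lower genes, and the wild-type pool for 25 higher genes, so those ratios rest in part on signals near background. Of the genes named here these were Ccl20, Cd3d, Cd5, Gbp3, Ms4a1, Pmaip1, Pou2af1, Reg3g, S100a9 and Tgtp1 on the lower side, and Cox8b, Defb29, Scgb1b27, Sval1 and Ucp1 on the higher side. Both pools were well above background on both arrays for the other 126 higher genes and for 266 lower ones. In the alternative that takes only probes detected in both pools, 126 genes were higher and 267 lower. After the sign of 1 array was turned, 58 genes passed the rule, or 9.03% of the 642 called genes. Turning a sign keeps the dye effects that the mean of the arrays cancels, so this is not a rate of false calls. Across genes, which are not independent replicates, the log2 ratios of the arrays correlated at Pearson r = 0.513 and Spearman rho = 0.157. The SD of the mean log2 ratios across genes was 0.52, and each array lay a median of 0.17 from the mean of the arrays.

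**Figure D1:**
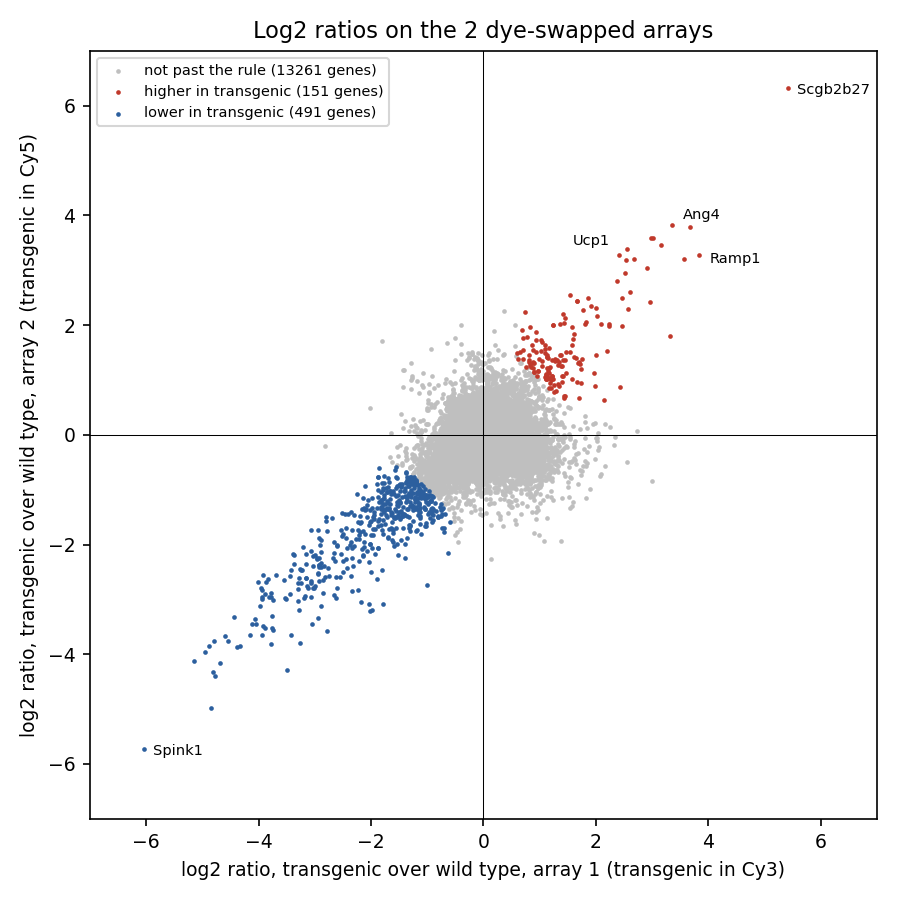
Log2 ratio of transgenic over wild type on array 1 (x axis, transgenic pool in Cy3) against array 2 (y axis, transgenic pool in Cy5), with 1 point per detected gene. The 151 higher genes (red) and 491 lower genes (blue) lie on the same side of 0 on both arrays, as the rule requires. Those with a usual symbol run from Spink1 at a mean of -5.88 to Scgb2b27 at 5.87. Genes not past the rule (grey) spread around 0.

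Among called genes with a usual symbol, the highest ratio was that of Scgb2b27, a member of the secretoglobin family of small secreted proteins, at a mean log2 ratio of 5.87 ± 0.63, or 58.5-fold. Another secretoglobin, Scgb2b20, was higher by 3.29 ± 0.43. The angiogenin ribonucleases Ang4 (3.59 ± 0.32), Ang (3.31 ± 0.22) and Ang2 (2.85 ± 0.61) were also among the 12 highest, as was the beta-defensin Defb29 at 3.30 ± 0.41. Ramp1, an accessory subunit of calcitonin-family receptors, was higher by 3.56 ± 0.38, and its other probe gave 2.22. Tff3, a trefoil peptide secreted by goblet cells, was 10.5-fold higher at 3.39 ± 0.25. Arg1, the arginase of the urea cycle and of some macrophages, was higher by 2.98 ± 0.10, and Fxyd4, a regulator of the sodium pump, by 2.94 ± 0.38. Ucp1, the uncoupling protein of brown fat, was higher by 2.96 ± 0.59, and Cox8b, a cytochrome oxidase subunit of muscle and brown fat, by 2.86 ± 0.46, each against a wild-type signal well above background on 1 of the 2 arrays. Secretoglobins and ribonucleases have close paralogs, and their probes were not checked for signal shared between family members.

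On the lower side, among called genes with a usual symbol and by the probe used for each, the lowest ratio was that of the trypsin inhibitor Spink1, at -5.88 ± 0.21, or 58.8-fold lower. The related kallikrein inhibitor Spink5 stood at -4.58 ± 0.27 and the elastase inhibitor Slpi at -3.90 ± 0.35. Msln, the cell surface protein mesothelin, was at -4.57 ± 0.35. The acute-phase protein Saa3 was at -4.14 ± 0.66, lactoferrin (Ltf) at -3.90 ± 0.56 and the antibacterial lectin Reg3g at -3.71 ± 0.50. Of these, Ltf is also in the neutrophil and mast cell list, and Saa3 in the inflammatory list. The remaining 5 of the 12 lowest genes belong to the immune system as well. They were the B-cell genes Cd79b (-3.80 ± 0.20), Ms4a1 (-3.70 ± 0.30) and Jchain (-3.54 ± 0.15), the chemokine Ccl8 (-3.65 ± 0.13) and the interferon-inducible GTPase Iigp1 (-3.63 ± 0.17). The other, dimmer probe of Jchain gave -5.98.

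**Figure D2:**
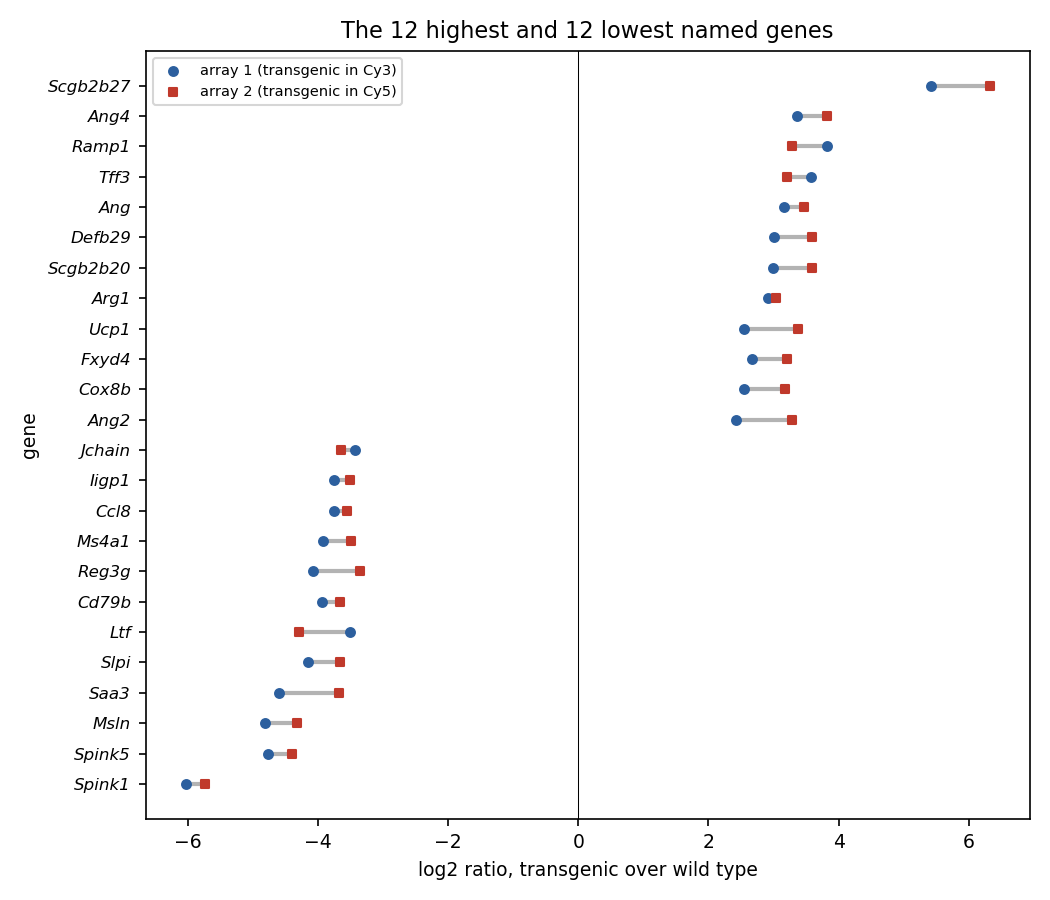
Log2 ratio of transgenic over wild type (x axis) of the 12 highest and 12 lowest named genes (y axis), with array 1 as a circle, array 2 as a square and a grey line joining them. The arrays lie on the same side of 0 for each gene, as the rule for called genes requires. The genes run from Spink1 at -6.03 and -5.73 to Scgb2b27 at 5.42 and 6.32.

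Markers of lymphocytes, macrophages and antigen presentation were lower in the transgenic pool. Of 12 detected B and plasma cell genes, 8 were lower and 0 higher, with a list median of -1.58, and Pou2af1, a B-cell transcriptional coactivator, was at -2.92 ± 0.17. Among 10 T and NK cell genes 6 were lower, with a median of -1.27. That median was -0.42 with no filter on dim probes and -2.51 with Feature Extraction's ratios. Icos stood at -1.56 ± 0.34 by its brighter probe, while its other probe gave -0.78. Its bound of at least 2.95-fold equals the measured mean ratio, and array 2 alone gave a smaller difference of -1.32. Cd3d stood at -1.52 ± 0.03, Cd5 at -1.52 ± 0.37 and Nkg7 at -1.52 ± 0.17, with -0.31 by the other probe of Nkg7. In the transgenic pool Cd3d and Cd5 were well above background on 1 of the 2 arrays, and with detection in both pools the list was too short to place among random lists. Of 17 macrophage and dendritic cell genes, 10 were lower, with a median of -1.25, including the lysosomal protease Ctss (-2.62 ± 0.61), lysozyme (Lyz2, -2.17 ± 0.05), Aif1 (-1.79 ± 0.40) and Mpeg1 (-1.51 ± 0.27). The MHC class II list had a median of -2.18, with 7 of 8 genes lower. In it, H2-Ab1 was at -2.94 ± 0.27, H2-Aa at -2.87 ± 0.02, the invariant chain Cd74 at -2.56 ± 0.74 and H2-DMa at -2.19 ± 0.26. The medians of all 4 lists lay at the 0th percentile of random lists. The B and plasma cell median was -3.68 with Feature Extraction's ratios, -3.74 in the series table and -2.74 with detection in both pools. Of 3 detected neutrophil and mast cell genes, S100a9 (-2.40 ± 0.14) and Ltf were lower, with a median of -2.40, a list too short to place among random lists. The second detected probe of Mpeg1 gave 0.19, against -1.51 for the probe used.

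Inflammatory cytokine and chemokine genes followed the same direction, with 9 of 19 lower, 0 higher and a median of -0.85 at the 0th percentile, which was -2.20 with Feature Extraction's ratios and -1.51 in the series table. The serum amyloids Saa1 (-3.003 ± 0.427) and Saa2 (-2.08 ± 0.53) and the chemokine Ccl20 (-2.50 ± 0.01) were among them. The interferon response list did not stand apart, with a median of -0.05 at percentile 18.03. The median was -0.09 on array 1 alone, -0.19 on array 2 at percentile 3.57, and 0.03 with Feature Extraction's ratios. In it 6 genes were lower, among them the GTPases Gbp2 (-2.08 ± 0.26) and Gbp3 (-1.96 ± 0.21) and the immunoproteasome subunits Psmb8 (-1.67 ± 0.04) and Psmb9 (-1.54 ± 0.28). Irf1 was lower as well at -1.06 ± 0.09, and the only higher gene was Ifit1 at 1.51 ± 0.14. The lower calls of both of these lists stood beside a median of -1.45 over the 47 detected members of the 4 leukocyte lists.

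Proliferation genes were lower as a list, with a median of -0.60 at the 0th percentile, which was -1.23 with Feature Extraction's ratios and -0.99 in the series table. Of 24 detected members 21 were below 0 on both arrays, but 3 passed the rule and 0 were higher. These were the survivin gene Birc5 (-1.39 ± 0.22), the proliferation antigen Mki67 (-1.35 ± 0.45) and the replication helicase subunit Mcm5 (-1.02 ± 0.29). Under median centring in place of loess, Mki67 and Mcm5 no longer passed. The same pool had the lower leukocyte medians of -1.25 to -2.18 given above, and leukocytes also express cell cycle genes.

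The 20 detected genes named in earlier literature as targets of miR-32 or its seed family had a median of -0.25, at percentile 0.11 of random lists. None of the 20 passed the rule in either direction (0 higher and 0 lower), and 12 were below 0 on both arrays. Btg2, an antiproliferative transcription cofactor, stood at -0.14 ± 0.08, and Pik3ip1, an inhibitor of PI3-kinase, at -0.27 ± 0.06. The proapoptotic gene Bcl2l11 was at -0.47 ± 0.29. The miR-32 host gene Tmem245 was not detected, and its probe does not measure the microRNA from the transgene.

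Products of the prostate epithelium went both ways. Of 13 detected ventral prostate secretory genes, 5 were lower and 1 was higher. The lower genes were Spink1, lipocalin 2 (Lcn2, -3.53 ± 0.39), Wfdc3 (-1.44 ± 0.55), the spermine-binding protein gene Sbp (-1.35 ± 0.55) and Sbpl (-1.04 ± 0.38), and the higher gene was Spink8 (2.48 ± 0.01). The list median was -0.20 at percentile 0.78, but it was -0.78 on array 1 and 0.20 on array 2, and 0.19 under median centring, so its direction was not settled. Probasin (Pbsn), whose promoter the transgene is built on, stood at 0.02 ± 0.50. The 26 androgen-regulated genes had a median of -0.17 at percentile 0.14, or -0.26 on array 2 alone, with Spink1 and Sbp lower and 1 gene higher. Among 7 products of other prostate lobes and the seminal vesicle, the transglutaminase Tgm4 (2.12 ± 0.14) and Sval1 (2.43 ± 0.20) were higher, Ceacam10 was lower at -2.60 ± 0.36, and the median was -0.05, with 0.29 on array 1 alone and -0.15 on array 2.

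Cell type lists of the epithelium and stroma differed by less than those of leukocytes. The luminal list had a median of 0.23 at percentile 99.45, with 1 of 16 members lower (Prom1, -1.01 ± 0.33), 0 higher and Krt8 at 0.36 ± 0.38. On array 1 alone its median was 0.059 at percentile 65.7, and under median centring 0.36. Basal genes had a median of -0.41 at percentile 0.01, with 0 of 13 past the rule and Krt5 at -0.35 ± 0.37, and on array 1 or array 2 alone the list did not stand apart. Fibroblast and extracellular matrix genes had a median of -0.54 at the 0th percentile, which was -0.87 in the series table. There the complement gene C3 (-3.06 ± 0.17), Lum (-1.11 ± 0.09) and Col3a1 (-1.11 ± 0.05) were lower, out of 22. Another probe of C3 gave -0.55. Smooth muscle genes had a median of -0.34 at the 0th percentile with 0 of 16 past the rule, and on array 1 alone -0.15 at percentile 11.1. It was -0.53 on array 2 alone and -0.55 in the series table. Among proximal luminal genes, 3 were higher, among them Clu (2.60 ± 0.002) and Ppp1r1b (1.13 ± 0.45), and Ly6d was lower at -2.001 ± 0.021. Their median of -0.13 was 0.10 under median centring, -0.19 on array 1 alone and -0.0039 on array 2. Of 13 goblet cell and mucin genes, Tff3, Clca1 (2.02 ± 0.36) and Fcgbp (1.77 ± 0.28) were higher, 0 were lower and the median was 0.13 at percentile 93.6, or -0.11 on array 1 alone and 0.29 on array 2. The intestinal mucin Muc2 was not detected. In the adipose list Ucp1, Cidea (2.13 ± 0.30) and Thrsp (1.099 ± 0.150) were higher, with a median of 0.08 over 13 genes, or 0.20 on array 1 alone and 0.04 on array 2.

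**Figure D3:**
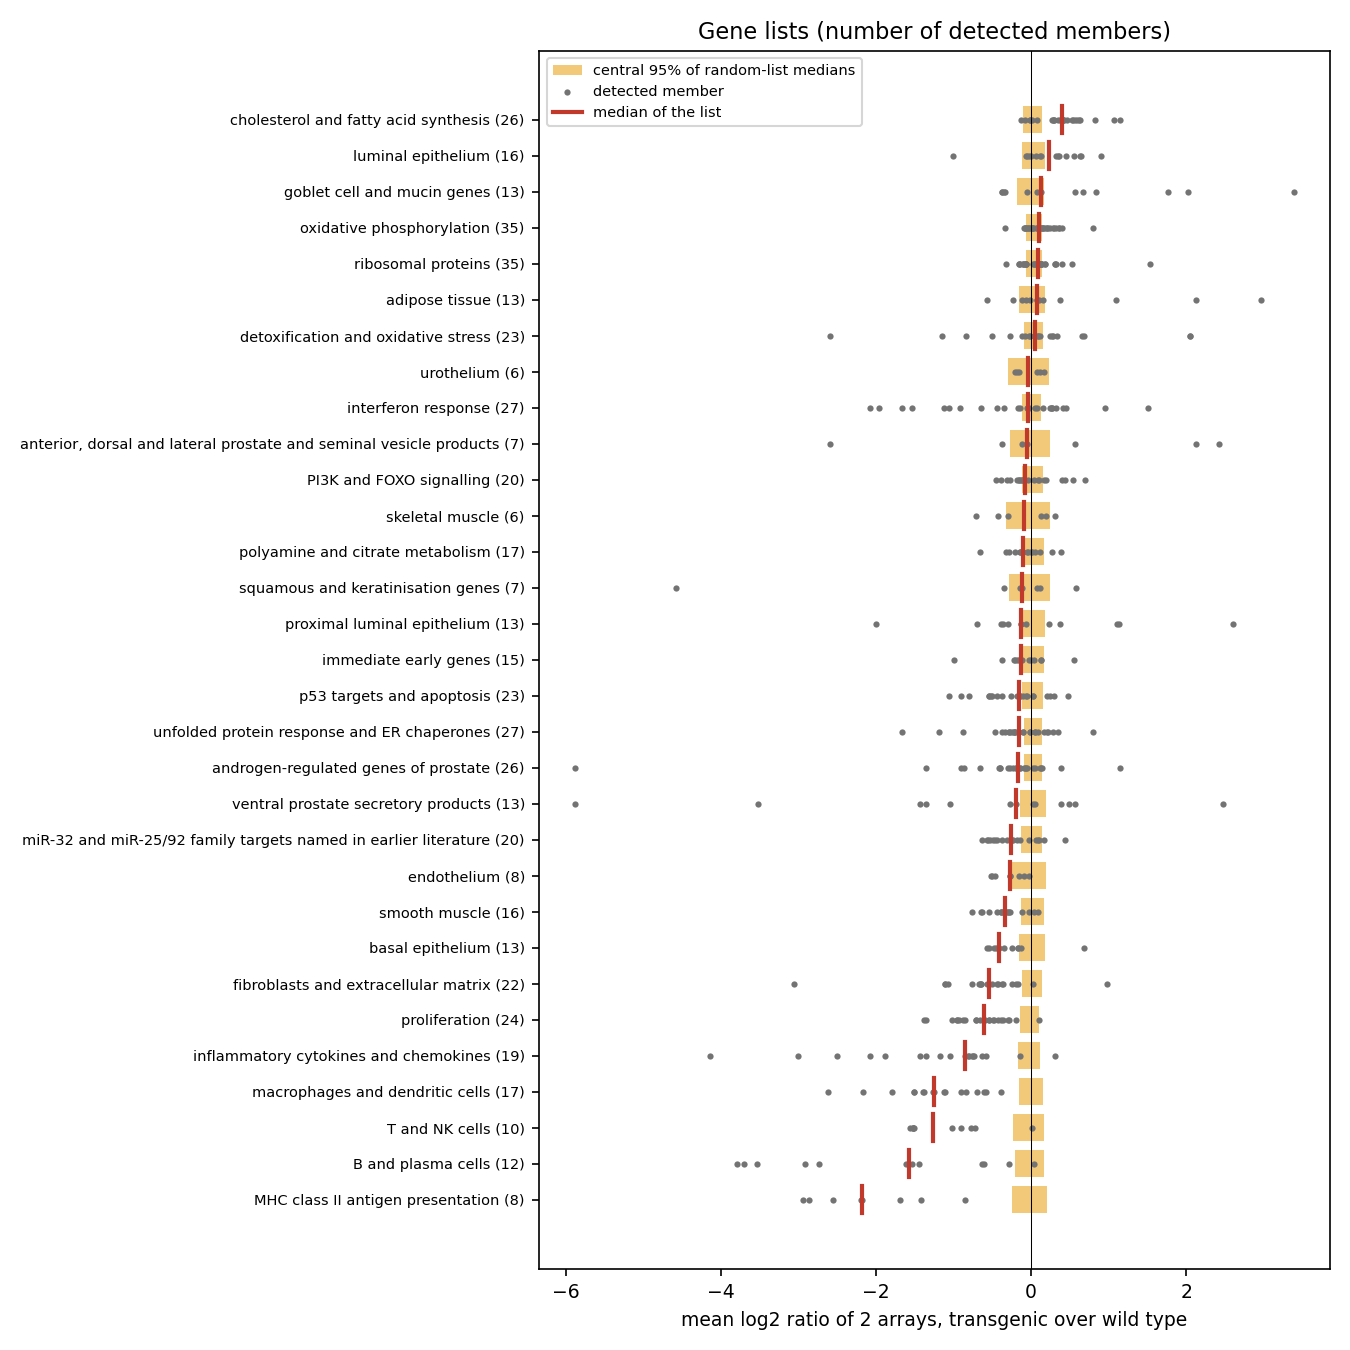
Mean log2 ratio of transgenic over wild type (x axis) of the detected members (grey points) of the 31 gene lists with at least 5 of them (y axis, number in parentheses), with the list median (red line) and the central 95% of medians of random lists (yellow). The lists run from MHC class II at a median of -2.18 to cholesterol and fatty acid synthesis at 0.40.

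Genes of cholesterol and fatty acid synthesis had the highest median of the 31 lists, 0.40, which lay at the 100th percentile. Of 26 members 18 were above 0 on both arrays and 1 passed the rule. Unfolded protein response genes had a median of -0.15 at percentile 0.19, with the chaperones Hspa5 (-1.67 ± 0.82) and Dnajb9 (-1.19 ± 0.03) lower, out of 27. This median was 0.0040 under median centring, still low against random lists at percentile 1.02, and -0.035 on array 1 alone, at percentile 38.1. The list of p53 targets and apoptosis had a median of -0.15 at percentile 0.78, with Pmaip1 lower at -1.06 ± 0.21. On array 2 alone that list did not stand apart, at -0.21 and percentile 3.48. In the detoxification list the metallothioneins Mt1 (2.05 ± 0.55) and Mt2 (2.04 ± 0.71) were higher, and the glutathione enzymes Gpx2 (-2.59 ± 0.85) and Gsta3 (-1.15 ± 0.30) were lower. Spink5 was the only called gene of the squamous list. Rps18 was the only called ribosomal gene, at 1.53 ± 0.02, and its other probe gave 0.46. Hspa5 and Rps18 did not pass the rule with Feature Extraction's own ratios.

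Medians of the other lists lay inside the central 95% of random lists, and none of their members passed the rule. They were -0.27 for endothelium, -0.13 for immediate early genes, -0.10 for polyamine and citrate metabolism, -0.09 for skeletal muscle, -0.07 for PI3K and FOXO signalling, -0.04 for urothelium and 0.11 for oxidative phosphorylation. Their directions were not all settled, with skeletal muscle at 0.09 on array 1 alone and -0.30 on array 2, and urothelium at 0.08 with detection in both pools. Immediate early genes were at -0.20 on array 1 alone and -0.02 on array 2, and PI3K and FOXO genes at -0.05 and -0.15. The nerve list with 4 detected genes and the blood list with 2 were too short to place, at medians of 0.06 and -0.22.

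In all, 16 of 31 lists stood apart, 2 higher and 14 lower. For lists of genes drawn independently, 1.55 would stand apart. Members of a list can vary together and some lists share genes, so 1.55 is not what chance would give for these lists. The counts of called genes depended on averaging the arrays. On array 2 alone 271 genes were higher and 589 lower at a 2-fold difference, and on array 1 alone 450 and 599, so that higher genes were 42.9% of the calls there against 23.5% in the mean of both. Among the genes named here, those that no longer passed the rule under median centring in place of loess were Mki67, Mcm5, Sbp, Sbpl, Prom1, Lum, Col3a1, Thrsp, Mpeg1, Psmb8, Dnajb9, Gsta3, Irf1 and Cox7a1. With the mean of a gene's probes, Nkg7 and Rps18 did not pass, nor did Prom1, Mpeg1, Dnajb9, Gsta3 and Irf1. On 1 of the arrays alone, or without background subtraction, the call was lost for Mcm5, Sbp, Sbpl, Prom1, Thrsp, Pmaip1, Ppp1r1b, Gsta3, Irf1 and Scgb1b27. Other detected probes would not pass a mean of 1 in size for Mki67 (-0.93), Dnajb9 (-0.44), Gsta3 (-0.81), Irf1 (-0.26) and Prom1 (-0.65).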

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

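The called genes that the naming rule took or that were chosen later, 89 in all, kept their direction under each alternative of processing or detection that measured them, while the rule itself fixes it on single arrays. Under median centring 72 of them still passed the rule, and under the others, single arrays among them, at least 82 of 89 or, where 73 were measured, at least 71. Under the other fold rules these genes were not counted. Of the 16 lists that stood apart, 10 did so in the same direction under each alternative that gave a value: proliferation, seed family targets, androgen-regulated genes, fibroblasts, T and NK cells, B and plasma cells, macrophages, MHC class II, inflammatory cytokines and cholesterol synthesis. Of the 15 lists that did not stand apart, 5 did so under at least 1 alternative. The causes of the changes below were not tested, except that single arrays lack the averaging of dye effects and that detection in both pools removes genes dim in 1 pool.

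The main counts were 151 higher and 491 lower genes. Feature Extraction's ratios gave 309 and 939, of which 610 were called in the main setting, where 642 were. Median centring gave 99 higher genes, and detection in both pools 267 lower ones. A single array gave 271 to 450 higher genes. A mean of 1.5-fold in the same direction gave 472 and 1078, and a mean of 3-fold 47 and 236. Other alternatives moved a count by less than 1.5 times. The correlation between arrays across genes was 0.513 in the main setting. It was 0.480 without background subtraction, 0.533 at offset 16, 0.747 with Feature Extraction's ratios, 0.223 with median centring, 0.609 in the series table, 0.422 with no filter, 0.393 with detection in both pools and 0.548 with the mean of probes.

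The ventral secretory median of -0.20 turned to 0.19 under median centring and ranged from -0.78 to 0.20 on single arrays. It no longer stood apart at -0.16 with Feature Extraction's ratios, at -0.23 in the series table and at -0.088 with no filter. The unfolded protein response median of -0.15 became 0.0040 under median centring, at percentile 1.02 of random lists. It was -0.090 with Feature Extraction's ratios, and ranged from -0.17 to -0.035 on single arrays. On single arrays the medians ranged from -0.28 to -0.22 for basal, 0.059 to 0.24 for luminal, -0.53 to -0.15 for smooth muscle, -0.212 to -0.207 for p53 target, -0.11 to 0.29 for goblet cell and 0.11 to 0.18 for oxidative phosphorylation genes, and each of these lists changed between standing apart and not. Endothelium stood apart at -0.26 without background subtraction, -0.28 with median centring, -0.19 with no filter and -0.27 against random lists not matched on intensity. Immediate early genes did at -0.12 with no filter and -0.13 with detection in both pools, and PI3K and FOXO genes at -0.13 with detection in both pools.

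The seed match comparison and its alternatives were not run, since it needs 3' UTR sequences. No paired analysis was possible because the arrays hold 1 pool per genotype. Signal over background limits the red channel most, where fewer spots were well above background than in green.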

Other observations

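The 4 gene families described here, and all tests below except that of unseen brown fat genes, were chosen after the values were seen. Among secreted ribonucleases, 7 of 9 detected genes were higher and 0 lower, with a median log2 ratio of 1.41, and the eosinophil-associated ribonuclease Ear1 stood at 2.05 ± 0.55 (SD, n = 2 technical arrays). Of 4 detected secretoglobins 3 were higher, with a median of 2.17, among them Scgb1b27 at 1.05 ± 0.48. Protease inhibitors of the Kazal and WAP classes, secreted proteins of mucosal epithelium, went mostly the other way, with 6 of 10 lower and a median of -1.79. Wfdc18 was at -3.17 ± 0.37, and Spink8 was the only higher member. Interferon-inducible GTPases were lower in 10 of 12 cases, with a median of -1.50, including Tgtp1 at -3.24 ± 0.06, whose transgenic signal was well above background on 1 of the 2 arrays, and Igtp at -2.25 ± 0.36. Over the 10 alternatives, each array alone among them, the medians ranged from 1.24 to 3.69 for ribonucleases, 1.84 to 4.74 for secretoglobins, -2.51 to -1.67 for the inhibitors and -2.80 to -1.33 for the GTPases, so no family turned its direction. Members of a family were chosen by symbol, and their probes can share signal.

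The 4 leukocyte lists hold 47 detected markers, of which 45 were lower on both dye orientations and 31 were called lower. The lists are T and NK cells, B and plasma cells, macrophages and dendritic cells, and MHC class II, which was not planned as a cell type list. Neutrophil and mast cell genes are left out. A dye effect changes sign with the swap. However, a marker detected in the wild-type pool alone tends to be lower by the filter itself, which can raise the share of 95.74%. The share alone thus cannot exclude noise of a single array or dye. With detection in both pools the medians were -2.74 for B and plasma cells, -1.39 for macrophages and -2.56 for MHC class II. These 3 still lay below the central 95% of random lists, and the T and NK list was too short to place. All 4 lists (4 of 4) lay below the central 95% of random lists. A smaller share of leukocyte RNA in the transgenic pool would give this. The outcome was known when the test was written, so it cannot decide for that reading. Genes outside these lists that leukocytes can express also went the other way. The eosinophil-associated ribonuclease Ear1 (2.05 ± 0.55), its relatives Ear10 (1.41) and Ear6 (1.33), and Arg1 (2.98 ± 0.10) were called higher. A uniform loss of leukocyte RNA would not give these, but the cells that express them here were not tested. Near 0 stood the T-cell gene Cd3e at 0.01 and Sdc1, a gene that epithelium also expresses, at 0.04, and 1 of the 47 markers (Xbp1, -0.29) is held by another list too. Whether the transgene, or inflamed glands in 1 or few of the pooled wild-type mice, lies behind the lower markers cannot be told apart, because there was 1 RNA pool per genotype.

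Rac2, a GTPase of blood cells, was at -1.70 ± 0.46, and Casp1, the inflammasome caspase, at -1.54 ± 0.45. Rac2 lay at percentile 27.66 of the detected leukocyte markers and Casp1 at percentile 36.17. Both genes were chosen after their values were seen, and a gene called lower tends to fall within the range of these markers. The percentiles thus cannot show whether their lower signals follow from the smaller leukocyte signal. A change within epithelial cells was not tested.

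Among called genes, 5 typical of brown fat were higher, with Fabp3 at 1.79 ± 0.49 and Cox7a1 at 1.53 ± 0.17 beside Ucp1, Cox8b and Cidea. They were named because they were called, so they do not stand for brown fat genes as a group. The fat cell genes Adipoq (0.10 ± 0.03) and Plin1 (0.07 ± 0.04) lay far below these, which argues against a larger share of the same fat tissue as in the wild-type pool. For brown fat itself, 12 detected genes from a list not looked at before had a median of 0.1176, at percentile 90.5 of random lists, with 0 called. A small amount of brown fat could not be excluded or shown by this, since most of these genes are also expressed in other tissues. Expression of Ucp1 and its partners by prostate cells was not tested.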
